A study of Drosophila melanogaster with 18 samples.

How the data were processed

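RNA was isolated from S2R+ cells and libraries were made from polyadenylated RNA with a directional kit, per the labels' protocols. The deposited files hold whole-number read counts per FlyBase gene ID, not normalized, 1 file for each of the 18 libraries. The submitters' processing notes name STAR 2.5.1b, featureCounts 1.5.1 and the build BDGP6. The annotation release and the settings for strand, multiply mapped reads and overlapping genes are not given in the sources used here. A gene that overlaps an antisense or neighbouring gene, or that has a near-identical copy (such as the Hsp70 genes), therefore has an uncertain count. Of 17559 IDs, 17253 were found in the Ensembl annotation of the same assembly name. The other 306 had no name there, held 4.83% of all counts, stayed in the tests and are given by ID only. Positions come from that annotation.

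Libraries were assigned to groups from the treatment label. Total counts per library were 15743484 to 18100792, and the common biological coefficient of variation between libraries of a group was 0.0432. Replicates differed by more than sampling noise, with a chi-square per degree of freedom between 2.33 and 15.7, so all 18 were kept as separate samples.

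Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr, which kept 8146, libraries were scaled by TMM, and a robust quasi-likelihood model was fitted to all 18 libraries with 1 coefficient per group. Contrasts were each of the 5 knockdowns against the control, CG7358 against each other knockdown, Ime4_dMettl14 against the mean of Fl2d, Vir and Nito, and an F test among the 6 groups. P-values were adjusted by Benjamini and Hochberg over the genes tested within a contrast, and a gene was called at adjusted p under 0.05. The SE of a log2 fold change is its size divided by the square root of the F statistic. A count over 1.5-fold is a count of called genes whose estimate exceeds that fold, not a test against it. CPM are scaled by TMM library sizes, and the log2 CPM of the principal component analysis used a prior count of 2.

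The groups, contrasts, alternatives, the 27 gene lists and the rule for named genes were fixed before the data were examined. The lists cover pathways, complexes and cell type markers, and 23 of their members were not matched to an ID. Lists with at least 5 tested members were tested with camera and fry from limma 3.58.1, with a preset correlation of 0.01 and with an estimated one, adjusted over lists within a contrast. A pair of lists with 4 tested members each were not tested as lists. Of 33 calls of a list in a knockdown against control with the preset correlation, 3 held with an estimated correlation: the m6A genes in Ime4_dMettl14 and Fl2d, and the cell cycle list in Ime4_dMettl14. The m6A list holds the targeted genes, which the treatment itself lowered, and was not tested without them. Its calls therefore do not show a change of the other members. Named genes are every m6A writer and reader gene, the 8 highest and 8 lowest called genes of each knockdown against control with an average log2 CPM of at least 3 and no overlap between knockdown and control libraries, up to 4 called members of each list with the smallest p, 6 risen and 6 fallen genes called in all 5 knockdowns, and 4 per direction in each direct comparison. Not all of them are given, some genes are not reported here, and most whose call was lost on leaving out a library are left out. The text names no gene outside this rule except those of dosage compensation in the closing section.

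The test was checked on simulated counts for CG7358 against control, run on 7926 genes with 50 genes at each of 4 fold sizes. It recovered 76% of genes changed by 1.25-fold, 84% at 1.5-fold, 90% at 2-fold and 98% at 4-fold, with 7 false among 181 calls and 0 calls in an unchanged group. Overlaps of calls were compared with 20 simulations in which all 18 libraries, controls included, were drawn from the control means with the dispersion of each gene, so that no group differed and all comparisons shared the simulated controls. The alternatives were DESeq2 size factors, DESeq2 1.42.0 as the test, no filter on low counts, a filter at a CPM above 5 in 3 libraries, the replicate number as a block, a test against a 1.5-fold change (glmTreat), only the groups compared in the fit, and each library left out in turn.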

Results

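Gene expression was measured by sequencing polyadenylated RNA from S2R+ cells, an adherent line derived from Drosophila embryonic cells with features of blood cells. Cells received 10 µg of double-stranded RNA in 3 treatments over 6 days, which lowers the matching transcript by RNA interference. There were 6 groups of 3 libraries: a control treated against LacZ, a bacterial gene, and knockdowns named Ime4_dMettl14, Fl2d, Vir, Nito and CG7358. All of these proteins are known parts of the complex that places N6-methyladenosine (m6A) on messenger RNA. Ime4 and dMettl14, annotated as Mettl3 and Mettl14, are the methyltransferase pair, and CG7358 is annotated as Flacc. Total counts per library ranged from 15743484 to 18100792, and 8146 genes passed the filter on low counts. The labels do not say that the libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. Each target was lowered in a single group, and no group restored it. Effects of the double-stranded RNA on other transcripts therefore cannot be told apart from effects of losing the target.

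Each targeted transcript was lowest in the group treated against it. Relative to the control mean, Mettl3 was at 10.5% and Mettl14 at 14.5% in Ime4_dMettl14, fl(2)d at 16.8% in Fl2d, vir at 12.3% in Vir, nito at 24.9% in Nito and Flacc at 29.6% in CG7358. Mettl3 (FBgn0039139, chromosome 3R, 24032157 to 24034257) went from 32.2 ± 0.422 to 3.39 ± 0.613 CPM, the counts scaled to library size (SD, n = 3). Mettl14 (FBgn0032016, 2L, 8308427 to 8309961) went from 49.0 ± 2.07 to 7.08 ± 0.568 CPM. For fl(2)d (FBgn0000662, 2R, 13819624 to 13824553) the levels were 176 ± 4.59 and 29.5 ± 2.33 CPM, and for vir (FBgn0003977, 2R, 23360192 to 23366355) 89.7 ± 1.51 and 11 ± 0.123 CPM. The transcript of nito (FBgn0027548, 2R, 7962463 to 7969805) went from 164 ± 3.01 to 41.0 ± 0.886 CPM and that of Flacc (FBgn0030974, X, 18888978 to 18893636) from 41.8 ± 2.22 to 12.4 ± 1.08 CPM. In edgeR's quasi-likelihood test all 6 decreases passed the threshold, with the weakest for Flacc (log2 fold change −1.76 ± 0.14 SE, adjusted p = 2.92e-07).

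The fl(2)d transcript rose in every knockdown that was not aimed at it. It reached 122% of control in Ime4_dMettl14 (log2 fold change 0.28 ± 0.03 SE, adjusted p = 1.17e-06 by edgeR), 133% in Vir (0.41 ± 0.03), 143% in Nito (0.52 ± 0.03) and 131% in CG7358 (0.39 ± 0.03). In the Nito knockdown other m6A genes rose as well: vir to 124%, Flacc to 127%, Mettl3 to 117%, Hakai, an E3 ligase of the complex, to 117%, and Ythdc1, the nuclear m6A reader, to 132% of control. Mettl3 reached 117% in Vir too. The reader Ythdf passed the threshold in none of the 5 knockdowns by edgeR, with log2 fold changes between −0.08 and 0.01. Of the 9 genes in the m6A list, which holds the targets, 1 rose and 2 fell in Ime4_dMettl14 and in Fl2d, and 2 rose and 1 fell in Vir, with the same counts when adjusted over the list alone. Limma's camera gave adjusted p = 1.29e-37, 1.07e-07 and 0.00516 in these knockdowns, and adjusted p = 7.37e-07, 0.00392 and 0.143 with an estimated correlation. In Vir the list's median log2 fold change was 0 and its mean −0.29. In Nito 6 of the 9 rose and 1 fell, also over the list alone, where 2429 of all 8146 tested genes rose. Camera gave adjusted p = 0.794 for the list in Nito, and adjusted p = 0.901 with an estimated correlation. In CG7358 1 rose and 1 fell, also over the list alone (camera adjusted p = 0.72, adjusted p = 0.826 with an estimated correlation). In Fl2d the called members besides fl(2)d were Mettl3, which rose (0.19 ± 0.06, adjusted p = 0.0115), and Ythdc1, which fell (−0.13 ± 0.05, adjusted p = 0.0466). For Mettl3 the adjusted p was 0.0528 without control replicate 1 and 0.105 without Fl2d replicate 1. For Ythdc1 it was 0.125, 0.0624 and 0.0772 without control replicate 1, 2 or 3, and 0.169 and 0.113 without Fl2d replicate 1 or 2.

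**Figure D1:**
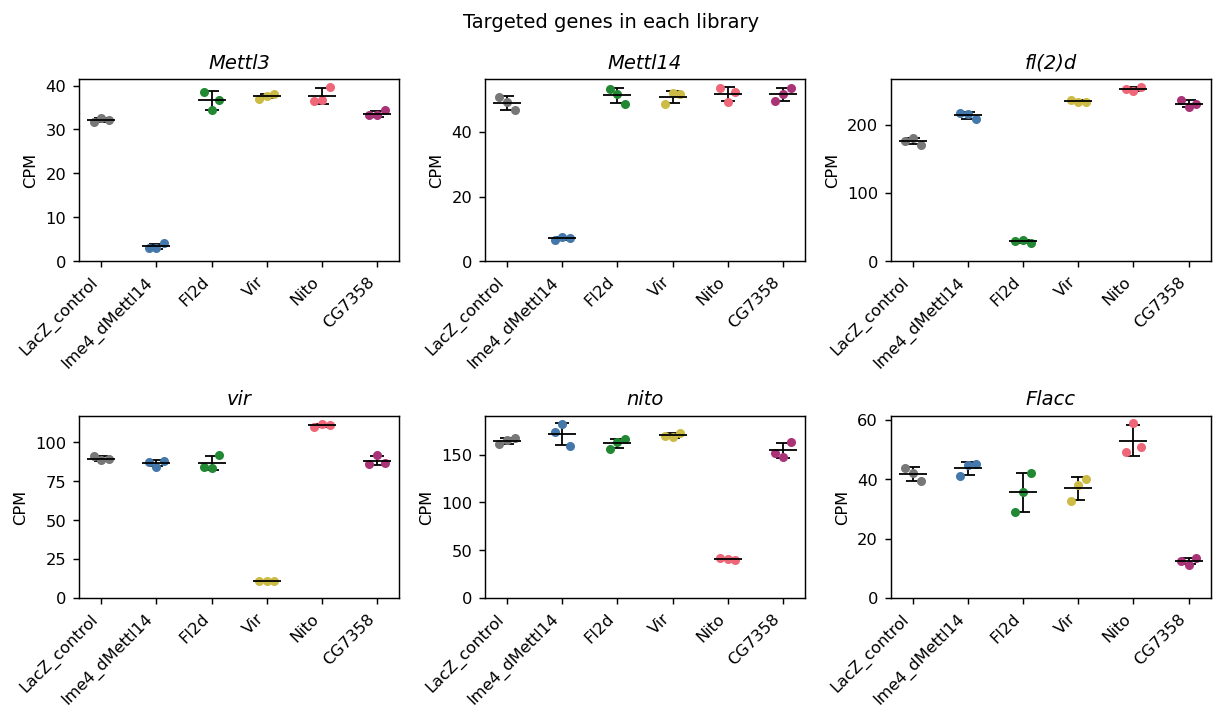
CPM of the 6 targeted genes in every library (points), with the mean and SD of each group of 3 (lines). Each gene is lowest in its own knockdown, and fl(2)d lies above the control in the other 4 knockdowns.

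Differences among the 6 groups covered most of the genes tested. In edgeR's F test 6267 of 8146 genes differed among the groups. On a principal component analysis of log2 CPM the first component held 41% of the variance and set the Nito libraries (30.9 to 32.6) apart from all others (−13.0 to −1.30). The second component, with 15.3%, placed Fl2d, Vir and CG7358 (−11.8 to −3.70) away from the control and Ime4_dMettl14 (7.62 to 11.8). More genes had at least 1 count in the Nito libraries (11156, 11161 and 11312) than in any other library (10366 to 10847). Mitochondrial transcripts took 2.01% to 4.06% of counts and varied within groups, for example 2.23%, 3.62% and 3.80% in the 3 control libraries.

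**Figure D2:**
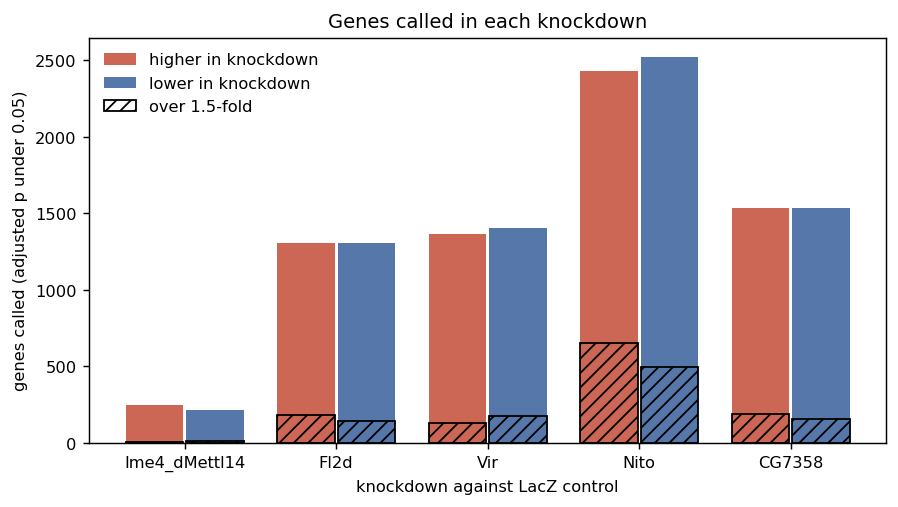
Number of genes called at adjusted p under 0.05 in each knockdown against the control, higher and lower, with those over 1.5-fold hatched. The counts go from 459 in Ime4_dMettl14 to 4948 in Nito.

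The Ime4_dMettl14 knockdown asked which transcripts change when the methyltransferase pair itself is lowered. Beyond the targets, few genes changed by more than 1.5-fold. Among genes with an average log2 CPM of at least 3 and no overlap between knockdown and control libraries, which here and in the other knockdowns are the ones ranked by size, CG15784 had the highest log2 fold change (log2 fold change 1.05 ± 0.09 SE, adjusted p = 8.63e-06), followed by drpr, the engulfment receptor Draper (0.77 ± 0.05, adjusted p = 6.21e-14). Among other genes that rose were CG10063 (0.46 ± 0.07), the matrix protein gene Ppn (0.46 ± 0.07), Kal1 (0.38 ± 0.07) and RpS19b (0.38 ± 0.05). Nt5b (−0.64 ± 0.05), CG15211 (−0.64 ± 0.05), Plc21C, a phospholipase C (−0.54 ± 0.06), pdgy (−0.52 ± 0.05) and Hrb98DE, an hnRNP protein (−0.47 ± 0.03, adjusted p = 1.66e-13), fell. Genes of the cell cycle and DNA replication fell in 9 of 40 measured members, and 12 when adjusted over the list alone, while 1 rose (1 over the list alone). Examples are the replication helicase genes Mcm5 (−0.20 ± 0.04) and dpa (−0.15 ± 0.03), and the list stood below other genes (limma's camera, adjusted p = 6.38e-05, and adjusted p = 0.0428 with an estimated correlation). Of 18 genes of the unfolded protein and integrated stress response 6 rose, 7 when adjusted over the list alone, among them the chaperone Hsc70-3 (0.24 ± 0.03), crc (0.18 ± 0.03), Xrp1 (0.13 ± 0.03) and Ire1 (0.18 ± 0.04), but camera gave adjusted p = 0.0863, upward, with a list median of 0.03 and a mean of −0.003. Further single genes that changed were Socs36E of the JAK/STAT pathway (0.26 ± 0.03), RpL7A (−0.40 ± 0.03), LanB1, a laminin chain (−0.39 ± 0.04), and AcCoAS, which makes acetyl-CoA (−0.33 ± 0.04).

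By edgeR 459 genes were called, 245 higher and 214 lower, of which 18 exceeded 1.5-fold. The count was 267 without control replicate 1, 250 without control replicate 2, 233 without Ime4_dMettl14 replicate 1 and 238 without Ime4_dMettl14 replicate 2.

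The Fl2d knockdown asked which transcripts change when Fl(2)d, the fly counterpart of WTAP, is lowered. CG15784 rose by 2.68 ± 0.09 (log2, SE; adjusted p = 9.58e-11), lncRNA:CR43963 by 2.06 ± 0.17, drpr by 1.66 ± 0.04, mamo by 1.61 ± 0.31 and AdamTS-B, a metalloprotease gene, by 1.21 ± 0.08. The genes with the lowest log2 fold change after fl(2)d were CG34330 (−1.38 ± 0.24), the monooxygenase gene Fmo-2 (−1.37 ± 0.07), CG9521 (−1.33 ± 0.33), CG15820 (−1.28 ± 0.09), fok (−1.24 ± 0.15), betaTub97EF (−1.19 ± 0.06) and Ncc69 (−1.15 ± 0.08). Unr, an RNA-binding protein gene with a role in dosage compensation, passed the threshold (2.40 ± 0.69, adjusted p = 0.0189) through replicate 2 of Fl2d, at 221 CPM against 35.6 and 33.3 in the other replicates and 12.9 to 21.5 in the controls. Without Fl2d replicate 2 its log2 fold change was 0.91 (adjusted p = 0.0912), and without control replicate 1 it was 2.18 (adjusted p = 0.0698). Genes FBgn0262735 (1.72 ± 0.46) and FBgn0013984 (1.66 ± 0.47), which had no symbol in the annotation used, went the same way, at 0.78 and 1.29 without Fl2d replicate 2 (adjusted p = 0.0386 and 0.0731) and at 1.58 and 1.52 without control replicate 1 (adjusted p = 0.0507 and 0.0649).

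Of 77 cytosolic ribosomal protein genes 65 rose in Fl2d and 0 fell (67 rose when adjusted over the list alone), for example RpS6 (0.31 ± 0.04), RpS27 (0.26 ± 0.03) and RpS5a (0.24 ± 0.03). Camera gave adjusted p = 1.99e-11 with its preset correlation and adjusted p = 0.35 with an estimated correlation. Glycolysis fell in 10 of 15 genes, 12 when adjusted over the list alone, including Pfk (−0.30 ± 0.05), Pgk (−0.20 ± 0.04) and Pglym78 (−0.30 ± 0.06), and 1 rose, also 1 over the list alone (camera adjusted p = 0.00797, adjusted p = 0.35 with an estimated correlation). Lipid synthesis genes fell in 7 of 16, also 7 when adjusted over the list alone. Among them were AcCoAS (−0.75 ± 0.04) and the phosphatidate phosphatase Lpin (−0.34 ± 0.04). SCAP rose (0.26 ± 0.03), the 1 member to do so, also 1 over the list alone. For that list camera gave adjusted p = 0.0117, and adjusted p = 0.327 with an estimated correlation. Plasmatocyte markers rose in 5 of 11 and fell in 1, with the same counts when adjusted over the list alone, with drpr, Fer1HCH (0.20 ± 0.03) and He (1.10 ± 0.22) (adjusted p = 0.000207, adjusted p = 0.0573 with an estimated correlation). Apoptosis genes rose in 4 of 17 and fell in 1, with the same counts when adjusted over the list alone, and those that rose were wgn (0.51 ± 0.04), egr (0.31 ± 0.03), Diap1 (0.27 ± 0.03) and puc (0.23 ± 0.03). Here egr and its receptor gene wgn are known to promote death signalling and Diap1 to restrain it (camera adjusted p = 0.00805, adjusted p = 0.0573 with an estimated correlation). Among axon guidance genes sli, which encodes the Slit ligand, rose by 1.14 ± 0.05, Dscam1 by 0.56 ± 0.04 and Abl by 0.42 ± 0.04, and unc-5 fell (−0.56 ± 0.05). In the Notch pathway fng, a glycosyltransferase acting on Notch, rose (1.18 ± 0.12) and O-fut1, which fucosylates it, fell (−0.81 ± 0.04). The integrin gene if fell (−1.07 ± 0.08) and so did Tig, encoding a matrix protein (−0.58 ± 0.04). By edgeR 2610 genes were called, 1306 higher and 1304 lower, 328 of them over 1.5-fold.

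The Vir knockdown asked which transcripts change when Virilizer, the fly counterpart of VIRMA, is lowered. CG15784 (2.62 ± 0.09), lncRNA:CR43963 (1.59 ± 0.18), CG12493 (1.17 ± 0.12), drpr (1.15 ± 0.04), sli (1.12 ± 0.05), Kal1 (1.03 ± 0.06), babos (1.03 ± 0.12) and fng (0.98 ± 0.13) rose. After vir itself the lowest were CG34330 (−1.49 ± 0.24), CG9521 (−1.46 ± 0.34), CG15820 (−1.37 ± 0.09), Fmo-2 (−1.37 ± 0.08), Inos, which encodes inositol-3-phosphate synthase (−1.32 ± 0.04, adjusted p = 9.56e-24), fok (−1.28 ± 0.15) and Targ1 (−1.17 ± 0.11). Cytosolic ribosomal protein genes rose in 56 of 77 and fell in 1 (61 and 1 when adjusted over the list alone), among them RpL7A (0.25 ± 0.03) and RpS5a (0.25 ± 0.03), with camera adjusted p = 3.75e-10 and adjusted p = 0.491 with an estimated correlation. Lipid synthesis genes fell in 8 of 16 and rose in 1, 9 and 1 when adjusted over the list alone, with AcCoAS (−0.80 ± 0.04), Lpin (−0.36 ± 0.04) and Pcyt1 (−0.27 ± 0.03) (adjusted p = 0.000971, adjusted p = 0.187 with an estimated correlation). Glycolysis fell in 8 of 15 and rose in 0, 8 and 1 when adjusted over the list alone, including Treh (−0.31 ± 0.04) and Pfk (−0.27 ± 0.05) (adjusted p = 0.0488, adjusted p = 0.491 with an estimated correlation). Heat shock and chaperone genes rose in 7 of 17, 9 when adjusted over the list alone, such as Hsp83 (0.19 ± 0.03) and lncRNA:Hsromega (0.29 ± 0.06) (adjusted p = 0.0314, adjusted p = 0.491 with an estimated correlation). In the JAK/STAT list Socs36E (0.47 ± 0.03) and the ligand gene upd2 (0.85 ± 0.13) rose, while et fell (−1.37 ± 0.23). Tig (−0.86 ± 0.04) and if (−0.96 ± 0.08) fell, and He rose (1.42 ± 0.21). By edgeR 2768 genes were called, 1362 higher and 1406 lower, 301 of them over 1.5-fold.

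The Nito knockdown asked which transcripts change when Spenito, the fly counterpart of RBM15, is lowered. It had the highest number of called genes among the 5 knockdowns. CG15784 rose by 4.09 ± 0.10 (log2, SE; adjusted p = 3e-13), lncRNA:CR44953 by 2.81 ± 0.09, CG42395 by 2.44 ± 0.09, fng by 2.12 ± 0.11, CG6569 by 2.02 ± 0.08, lncRNA:CR43963 by 1.98 ± 0.17, CG12493 by 1.83 ± 0.11 and babos by 1.74 ± 0.10. CG15211 (−2.96 ± 0.07), Apoltp, a lipid transfer protein gene (−2.70 ± 0.08), the carbonic anhydrase gene CAH7 (−2.68 ± 0.07), CG31522 (−2.65 ± 0.06), Stlk (−2.48 ± 0.08), Cubn, encoding cubilin (−2.35 ± 0.13), CG10365 (−2.28 ± 0.12) and Ant2 (−2.24 ± 0.08) were lowest. The RNA interference machinery rose in 8 of 16 genes and fell in 2, with the same counts when adjusted over the list alone, with pasha, a partner of Drosha (1.32 ± 0.05), Hen1 (1.06 ± 0.07), Dcr-2 (0.35 ± 0.03) and AGO2 (0.25 ± 0.03) as examples. For that list camera gave adjusted p = 0.0273, and adjusted p = 0.255 with an estimated correlation.

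In Nito heat shock and chaperone genes rose in 13 of 17, also 13 when adjusted over the list alone, including Hsp27 (1.07 ± 0.08), Hsp23 (0.88 ± 0.10) and lncRNA:Hsromega (0.84 ± 0.06) (camera adjusted p = 0.00223, adjusted p = 0.272 with an estimated correlation). Apoptosis genes rose in 10 of 17 and fell in 2, with the same counts when adjusted over the list alone, with the death activator rpr (1.24 ± 0.08) and the initiator caspase Dronc (0.59 ± 0.05) among them (adjusted p = 0.0298, adjusted p = 0.255 with an estimated correlation). Cell cycle and replication genes rose in 21 of 40 and fell in 3, with the same counts when adjusted over the list alone, for example Dp (0.41 ± 0.03), CycD (0.52 ± 0.04) and PCNA (0.30 ± 0.03) (adjusted p = 0.016, adjusted p = 0.255 with an estimated correlation). Splicing factors rose in 16 of 36 and fell in 1, among them U2af50 (0.48 ± 0.03) and mub (0.51 ± 0.04), and RNA decay and export genes rose in 15 of 24 and fell in 3, with the same counts adjusted over the list alone, such as pcm (0.49 ± 0.04) and Ref1 (0.39 ± 0.04). Camera gave adjusted p = 0.0298 and 0.0273 for these lists, and both had adjusted p = 0.272 with an estimated correlation. Extracellular matrix and integrin genes fell in 11 of 22 and rose in 3, with the same counts when adjusted over the list alone: Tig (−1.47 ± 0.04), Mmp2 (−1.08 ± 0.04), LanB1 (−0.98 ± 0.04) and LanB2 (−0.77 ± 0.03) (adjusted p = 0.000288, adjusted p = 0.201 with an estimated correlation). Glycolysis fell in 13 of 15 and rose in 1, 13 and 2 when adjusted over the list alone, with Pgm1 (−0.70 ± 0.08) and Pfk (−0.53 ± 0.05). Lipid synthesis fell in 11 of 16 and rose in 3, with the same counts when adjusted over the list alone, with mdy (−0.88 ± 0.07) and eas (−0.66 ± 0.04). For these lists camera gave adjusted p = 0.00939 and 0.0273, and adjusted p = 0.339 and 0.272 with an estimated correlation. Neuron markers rose in 6 of 11, also 6 over the list alone, with brp (1.86 ± 0.28), Gad1 (1.66 ± 0.42) and futsch (0.90 ± 0.10) (camera adjusted p = 0.105). Plasmatocyte markers fell in 6 of 11 and rose in 3, 6 and 4 when adjusted over the list alone, with a median log2 fold change of −0.13 (camera adjusted p = 0.205). AGO3 (−1.96 ± 0.10) and the scavenger receptor gene Sr-CI (−0.92 ± 0.05) fell. By edgeR 4948 genes were called, 2429 higher and 2519 lower, 1149 of them over 1.5-fold.

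The CG7358 knockdown addressed whether lowering Flacc, the fly counterpart of ZC3H13, goes with changes in the transcripts that change in the other knockdowns. CG15784 (2.35 ± 0.09), lncRNA:CR43963 (2.07 ± 0.17), Kal1 (1.35 ± 0.06), fng (1.23 ± 0.12), drpr (1.13 ± 0.04) and AdamTS-B (1.06 ± 0.08) rose. CG15820 (−1.36 ± 0.09), teq (−1.35 ± 0.09), Fmo-2 (−1.34 ± 0.07), CG5254 (−1.34 ± 0.09), CG34330 (−1.31 ± 0.24), axo (−1.21 ± 0.06) and CG6126 (−1.20 ± 0.08) were lowest after Flacc. The splicing factor gene B52 fell in CG7358 (−0.51 ± 0.04, adjusted p = 7.47e-13) and rose in Fl2d (0.16 ± 0.04), Vir (0.19 ± 0.04) and Nito (0.23 ± 0.04).

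In CG7358 cytosolic ribosomal protein genes rose in 42 of 77 and fell in 1, 50 and 1 when adjusted over the list alone, for example RpS6 (0.26 ± 0.04) (camera adjusted p = 5.15e-05, adjusted p = 0.597 with an estimated correlation). Cell cycle and replication genes fell in 21 of 40 and rose in 2, 21 and 3 when adjusted over the list alone, among them Klp61F (−0.25 ± 0.03), tum (−0.23 ± 0.03) and polo (−0.19 ± 0.03) (adjusted p = 0.00469, adjusted p = 0.154 with an estimated correlation). Lipid synthesis genes fell in 7 of 16 and rose in 2, 8 and 3 when adjusted over the list alone, with mdy (−0.80 ± 0.07) and AcCoAS (−0.66 ± 0.04) (adjusted p = 0.00817, adjusted p = 0.154 with an estimated correlation). Ecdysone response genes rose in 8 of 16, also 8 over the list alone, with Eip74EF (0.40 ± 0.05), Hr39 (0.40 ± 0.05) and the receptor gene EcR (0.33 ± 0.05), and apoptosis genes rose in 7 of 17 and fell in 1, 8 and 1 over the list alone, with rpr (0.54 ± 0.08), Drice (0.33 ± 0.04) and Diap1 (0.34 ± 0.03). Camera gave adjusted p = 0.00651 and 0.00485 for these lists, and adjusted p = 0.154 and 0.0962 with an estimated correlation. JAK/STAT genes rose in 4 of 10 and fell in 1, with the same counts adjusted over the list alone, with Socs36E (0.55 ± 0.03) and upd3 (0.52 ± 0.11). Unfolded protein and stress response genes rose in 9 of 18 and fell in 2, 9 and 3 over the list alone, with Gp93 (0.39 ± 0.03) and Xrp1 (0.30 ± 0.03), and crystal cell and lamellocyte markers in 6 of 8, also 6 over the list alone, with Tret1-1 (0.52 ± 0.05) and mthl4 (0.35 ± 0.05). Camera gave adjusted p = 0.00651, 0.0157 and 0.00825 for these, and adjusted p = 0.154 for each with an estimated correlation. Plasmatocyte markers rose in 6 of 11 and fell in 2 (camera adjusted p = 0.00651, adjusted p = 0.154 with an estimated correlation), heat shock and chaperone genes rose in 8 of 17 and fell in 0 (adjusted p = 0.0343, adjusted p = 0.451 with an estimated correlation), and axon guidance genes rose in 9 of 31 and fell in 5 (adjusted p = 0.0283, adjusted p = 0.597 with an estimated correlation), each with the same counts adjusted over the list alone. By edgeR 3064 genes were called, 1532 higher and 1532 lower, 342 of them over 1.5-fold.

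Genes called with one sign in all 5 knockdowns numbered 68 higher and 73 lower. The genes with the largest smallest change across the 5 were, among those that rose, CG15784, CG10063 (0.45 to 0.88 across the knockdowns), AOX1, an aldehyde oxidase gene (0.29 to 0.76), Cyt-c1L (0.30 to 0.94), and CG12099 (0.28 to 0.34). Those that fell were CG15211 (−2.96 to −0.64), Plc21C (−1.02 to −0.54), pdgy (−1.02 to −0.52), CG6126 (−1.20 to −0.41), Xxylt, a xylosyltransferase gene (−0.72 to −0.38), and the formin gene DAAM (−1.28 to −0.37). Fl2d, Vir and CG7358 shared 752 genes that rose and 734 that fell.

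Genes called in CG7358 and in another knockdown, with the same sign, were counted beside 2 references: the overlap of independent lists of those sizes, and a simulation of unchanged groups that share simulated controls, which gave 0 shared genes in each of 20 draws. Unchanged groups leave next to no calls to share, so that 0 sets no scale for the overlap of groups with effects. CG7358 and Ime4_dMettl14 shared 197 genes higher and 133 lower, where independent lists would share 46 and 40. With Fl2d the shared counts were 950 and 896 against 246 and 245, with Vir 921 and 930 against 256 and 264, and with Nito 783 and 844 against 457 and 474. Genes called in both with opposite signs numbered 26 with Ime4_dMettl14, 19 with Fl2d, 21 with Vir and 632 with Nito. No reference was computed for opposite signs. Across genes, which are not independent replicates, the covariance of log2 fold changes was 0.0221 with Ime4_dMettl14, 0.0723 with Fl2d, 0.0704 with Vir and 0.0841 with Nito, while the simulated covariance was 0.00947, 0.00948, 0.00942 and 0.00946. The correlation was 0.36, 0.75, 0.76 and 0.51, and 0.49, 0.49, 0.48 and 0.49 in the simulation. Without effects the simulated fold changes hold only noise, and the shared controls alone give that correlation. It therefore sets no scale for the correlation of groups with effects. The 3 control libraries were not divided between the comparisons, so part of the excess in shared genes may come from the shared controls. The simulated covariance includes the part that shared controls add. The overlap of CG7358 and Ime4_dMettl14, 330 genes, was 188 without control replicate 1, 172 without control replicate 2, 162 without Ime4_dMettl14 replicate 1 and 174 without Ime4_dMettl14 replicate 2.

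**Figure D3:**
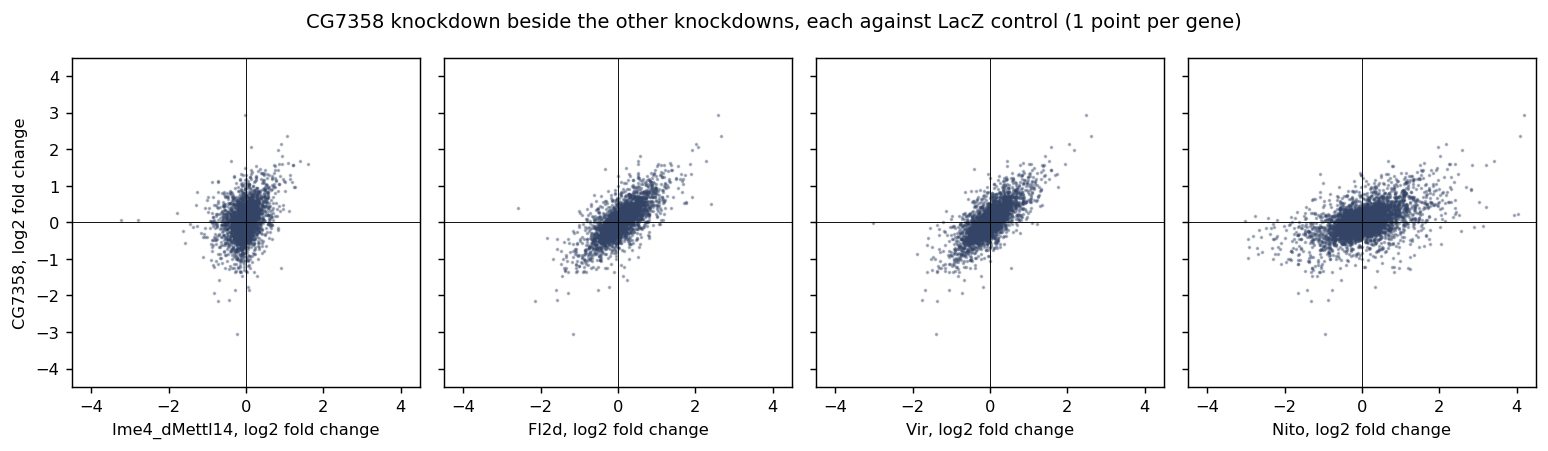
Log2 fold change of every tested gene in CG7358 (vertical axis) beside Ime4_dMettl14, Fl2d, Vir and Nito (horizontal axes), each against the LacZ control. The correlations across genes are 0.36, 0.75, 0.76 and 0.51, with the 6 targeted genes left out. Simulated groups without effects gave 0.48 to 0.49, which comes from the shared controls and sets no scale for groups with effects.

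The knockdowns were also set against each other directly, with the control libraries adding only to the estimate of spread. CG7358 against Fl2d differed in 958 genes, 527 higher and 431 lower, of which 79 exceeded 1.5-fold. Apart from the targets, O-fut1 (0.91 ± 0.04), CG8839 (0.90 ± 0.03) and Rubicon (0.85 ± 0.09) were higher in CG7358, while CG1317 (−0.85 ± 0.03), CG43188 (−0.75 ± 0.13) and Irp-1B (−0.73 ± 0.04) were lower. Notch pathway genes were higher in 4 of 13, also 4 when adjusted over the list alone (camera adjusted p = 0.000444, adjusted p = 0.199 with an estimated correlation). Cytosolic ribosomal protein genes were lower in 10 of 77 and higher in 1, with the same counts when adjusted over the list alone (adjusted p = 0.0107, adjusted p = 0.724 with an estimated correlation). The count was 621 without Fl2d replicate 1, 630 without CG7358 replicate 1, and 549 when only those 6 libraries were fitted.

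CG7358 against Vir differed in 1120 genes, 604 higher and 516 lower, 67 of them over 1.5-fold. Inos (0.97 ± 0.04), CG18135 (0.89 ± 0.13) and CG11378 (0.87 ± 0.09) were higher in CG7358, and CG1317 (−0.86 ± 0.03), qkr54B (−0.70 ± 0.04) and B52 (−0.70 ± 0.04, adjusted p = 1.08e-15) lower. Autophagy and lysosome genes were higher in 10 of 26, 12 when adjusted over the list alone, and 1 was lower, also 1 over the list alone. For that list camera gave adjusted p = 0.000154, and adjusted p = 0.00932 with an estimated correlation. Cell cycle and replication genes were lower in 6 of 40 and higher in 0, with the same counts when adjusted over the list alone (adjusted p = 0.00673, adjusted p = 0.158 with an estimated correlation). The count was 715 without Vir replicate 3.

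CG7358 against Ime4_dMettl14 differed in 2594 genes, 1309 higher and 1285 lower, 337 of them over 1.5-fold. lncRNA:CR43963 was higher (1.94 ± 0.17), and CG15820 (−1.38 ± 0.09), CG34330 (−1.25 ± 0.24) and teq (−1.20 ± 0.09) were lower in CG7358. Cytosolic ribosomal protein genes were higher in 54 of 77 and lower in 4, 57 and 4 when adjusted over the list alone (camera adjusted p = 3.69e-09, adjusted p = 0.344 with an estimated correlation). Lipid synthesis genes were lower in 8 of 16 and higher in 1, 9 and 3 when adjusted over the list alone (adjusted p = 0.00675, adjusted p = 0.202 with an estimated correlation). CG7358 against Nito differed in 4547 genes, 2345 higher and 2202 lower, 924 of them over 1.5-fold. CG31522 (2.44 ± 0.06), Stlk (2.34 ± 0.08), Cubn (2.19 ± 0.13) and AdamTS-B (2.06 ± 0.10) were higher in CG7358, and CG42395 (−2.16 ± 0.09), lncRNA:CR44953 (−1.94 ± 0.08) and gol (−1.78 ± 0.12) lower. Cell cycle and replication genes were lower in CG7358 in 30 of 40 and higher in 0, 30 and 1 over the list alone (adjusted p = 1.38e-06, adjusted p = 0.0279 with an estimated correlation). Extracellular matrix and integrin genes were higher in 13 of 22 and lower in 2, with the same counts when adjusted over the list alone (adjusted p = 0.000202, adjusted p = 0.103 with an estimated correlation).

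The Ime4_dMettl14 knockdown was also set against the mean of Fl2d, Vir and Nito. It differed in 3547 genes, 1853 higher and 1694 lower, with 509 over 1.5-fold. Ant2 (1.37 ± 0.06), CG9521 (1.36 ± 0.26), CG34330 (1.32 ± 0.18) and CG13654 (1.28 ± 0.05) were higher in Ime4_dMettl14, while CG15784 (−2.08 ± 0.08) and lncRNA:CR43963 (−1.74 ± 0.15) were lower, besides the targets. Cytosolic ribosomal protein genes were lower in 65 of 77 and higher in 2, 66 and 2 when adjusted over the list alone, and heat shock and chaperone genes in 12 of 17, also 12 over the list alone. Camera gave adjusted p = 3.36e-09 and 0.000424 for these lists, and adjusted p = 0.381 and 0.144 with an estimated correlation. Glycolysis was higher in 10 of 15, 12 when adjusted over the list alone, and lower in 0. Lipid synthesis genes were higher in 10 of 16 and extracellular matrix genes in 10 of 22, each with 2 lower and the same counts when adjusted over the list alone. Camera gave adjusted p = 0.00097, 0.00119 and 0.00155 for these lists, and adjusted p = 0.263, 0.144 and 0.144 with an estimated correlation. The mean does not stand for each of its 3 groups. Against control the extracellular matrix list had camera adjusted p = 0.205 in Fl2d, 0.265 in Vir and 0.000288 in Nito. For the ribosomal list it was 1.99e-11, 3.75e-10 and 0.251, and the heat shock medians were 0.196, 0.211 and 0.615.

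**Figure D4:**
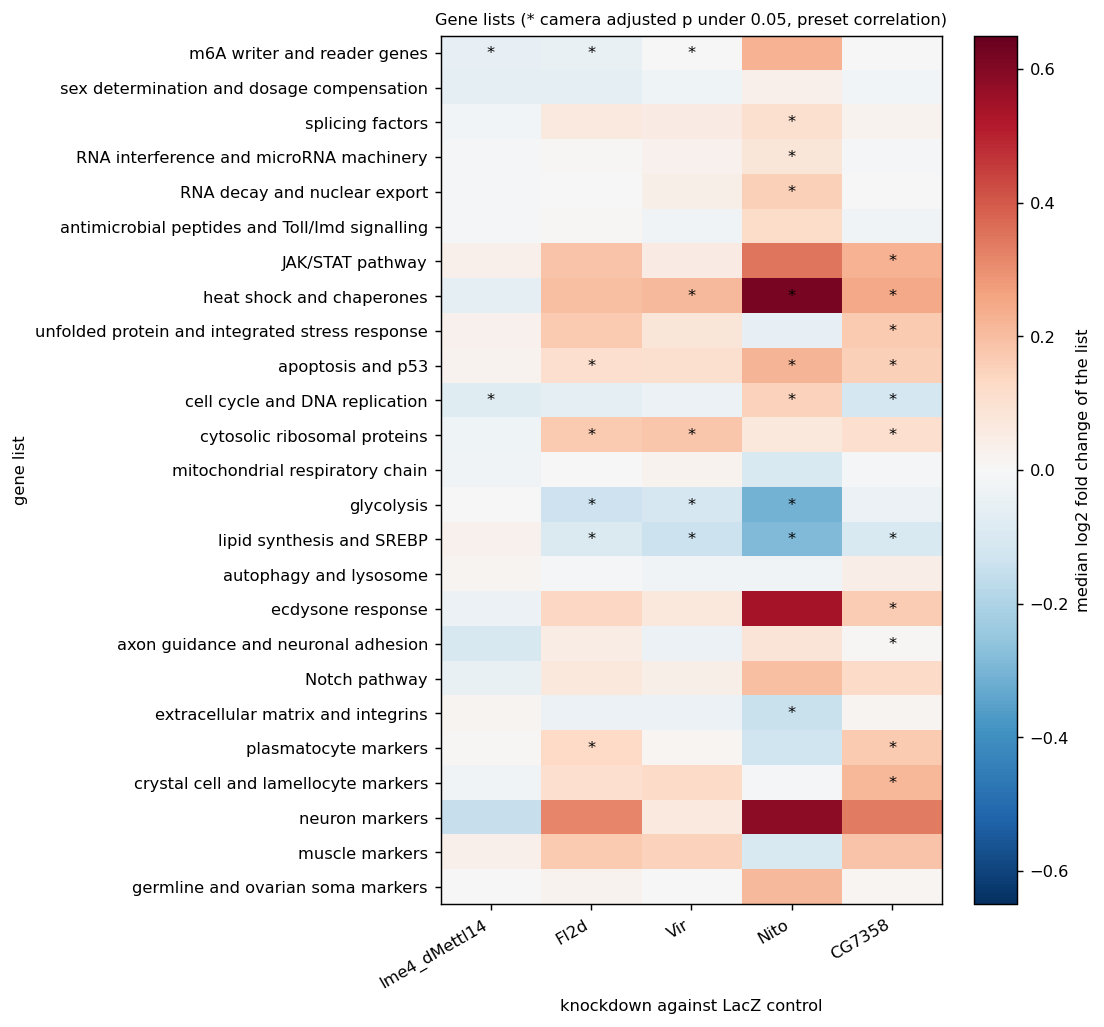
Median log2 fold change of each gene list with at least 5 tested members in the 5 knockdowns against control, as colour. A star marks camera adjusted p under 0.05 with the preset correlation, as for glycolysis in Fl2d (0.00797), Vir (0.0488) and Nito (0.00939), where the adjusted p = 0.35, 0.491 and 0.339 with an estimated correlation.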

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

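All alternatives here were chosen before the data were examined, and the counts over other splits were specified after the main counts were seen. Counts of called genes in the 5 knockdowns stayed within 1.5 times under DESeq2 size factors, DESeq2, no filter and a stricter filter. They ranged from 357 to 529 for Ime4_dMettl14, 2160 to 2622 for Fl2d, 2314 to 2775 for Vir, 4349 to 5007 for Nito and 2589 to 3078 for CG7358, with the fit of only the groups compared included. The same fit gave 549 genes for CG7358 against Fl2d, where 958 were called with all libraries. It holds fewer samples, but fewer samples did not lower every count. With the groups compared alone it was 493 instead of 459 for Ime4_dMettl14, and 4571 instead of 4547 for CG7358 against Nito. The other contrasts gave lower counts, such as 2183 instead of 2610 for Fl2d against control. The cause was not tested further. All 33 list calls in the knockdowns passed also with DESeq2 size factors, with the block and with fry. Without a filter 31 passed, and with an estimated correlation 3. Fry asks whether the members of a list change in a common direction, without setting them against other genes. It called 4, 16, 16, 18 and 14 of 25 lists in the 5 knockdowns in the order above. Camera with the preset correlation called 2, 6, 5, 9 and 11.

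A test against a 1.5-fold change, a stricter question by construction, left 4 genes in Ime4_dMettl14, 54 in Fl2d, 55 in Vir, 534 in Nito and 76 in CG7358. It left 53 for CG7358 against Ime4_dMettl14, 5 against Fl2d, 5 against Vir, 387 against Nito and 104 for Ime4_dMettl14 against the mean of the others. Genes shared by CG7358 were then 2 with Ime4_dMettl14, 35 with Fl2d, 35 with Vir and 46 with Nito. The rise of fl(2)d passed under every other alternative in the 4 knockdowns but not under this one, and all 6 target decreases passed under all of them.

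Leaving out 1 library, which leaves fewer samples, gave 233 to 364 genes for Ime4_dMettl14, 2113 to 2395 for Fl2d, 2219 to 2569 for Vir, 4500 to 4617 for Nito and 2605 to 2819 for CG7358. For CG7358 the ranges were 2077 to 2222 against Ime4_dMettl14, 621 to 1022 against Fl2d, 715 to 947 against Vir and 4194 to 4325 against Nito. They were 2845 to 3641 for Ime4_dMettl14 against the mean and 5930 to 6337 among the 6 groups. Shared genes ranged from 162 to 339 with Ime4_dMettl14, 1503 to 1730 with Fl2d, 1495 to 1766 with Vir and 1365 to 1527 with Nito. Of 525 named pairs of gene and comparison, 60 lost the call without some library, and 0 changed sign.

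With the replicate number as a block, counts were 458, 2576, 2756, 4923 and 3059 for the 5 knockdowns in the order above, so the block moved no count by more than 1.5 times. The numbers were not found to pair the libraries: the correlation of deviations over 45 same-number pairs lay between −0.0865 and 0.17 with 5 pairs over 0.1, and 9 of 18 libraries correlated best with their own number. Of the named calls 4 were lost under the block, 12 under DESeq2, 4 without a filter and 0 with DESeq2 size factors. At this depth the test recovered 84% of simulated 1.5-fold changes for CG7358 against control. The simulation gave 181 calls where the data gave 3064. With fewer calls the adjustment asks for a smaller p, so the recovery does not carry over directly to the data.

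With 3 libraries against 3 the 10 splits are too few for a share under 0.05. The real split gave 459, 2610, 2768, 4948 and 3064 genes for the knockdowns against control, and 2594, 958, 1120 and 4547 for CG7358 against Ime4_dMettl14, Fl2d, Vir and Nito. In each of these 1 split, the real one, was as large, and the highest other count was 0, or 1 for CG7358 against Fl2d and against Vir. Among the 6 groups 1 of 100 splits, the real one, was as large (6267 genes). The highest other count was 3989, in a split that kept the 3 Nito and the 3 control libraries together. That share argues against a random grouping of these libraries, not against differences between cultures. How to read the shares was set after the splits had been run. For Ime4_dMettl14 against the mean 2 of 100 were as large (3547, highest other 4602), and the larger one put the 3 Nito libraries in the place of Ime4_dMettl14. In both cases splits that mix the groups widen the spread within them, with a median of 0 genes. The second share, also under 0.05, likewise argues against a random grouping but does not test Ime4_dMettl14 itself. Because of the wider spread in mixed splits, both shares say only that some of the groups differ.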

Other observations

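The tests of X-linked genes as a set and of the dosage compensation genes were chosen only after the result was seen. X-linked genes stood higher than autosomal genes in the Nito knockdown. The median log2 fold change was 0.15 over 1401 X-linked genes and −0.03 over 6469 genes of the large autosome arms, and 655 X-linked genes (46.8%) rose while 253 (18.1%) fell, against 26.1% and 33.9% of the autosomal ones. In the other 4 knockdowns the difference of medians lay between −0.02 and 0.00. Per library, relative to the control mean, it was between 0.16 and 0.19 in the 3 Nito libraries and between −0.04 and 0.01 in the other 15. The 3 control libraries among those 15 make up that mean, so their values (−0.016, 0.008 and 0.008) are small by construction. Limma's camera gave p = 8.26e-05 for the X-linked set in Nito, and p = 0.0179 with an estimated correlation. The 83 tested genes of chromosome 4 had a median of 0.09.

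Exon length and expression level do not account for this shift as the whole cause. Over 25 strata of both, the difference was 0.162, and 0.144 to 0.173 in the single Nito libraries. The bootstrap 95% interval was 0.138 to 0.194. It was drawn over genes and does not measure the spread between libraries. Nor does the shift rest on 1 stretch of the chromosome. All 10 of 10 segments of about equal gene number lay above the autosomal median by more than 0.05, by 0.109 to 0.235. The dosage compensation genes did not rise together at the RNA level. Their rule was set after the values were known, so this describes them and is no test. Of 6 genes 1 rose, mle (0.12 ± 0.04), while lncRNA:roX2 fell (−0.66 ± 0.07, from 61.4 to 67.6 CPM in the controls to 39.9 to 41.0 in Nito). The genes msl-1, msl-2, msl-3 and mof lay between −0.03 and 0.10. A different number of X chromosomes in the Nito cultures and a change in dosage compensation at the protein level may both give such a shift and were not tested here.

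More genes had a count in the Nito libraries, and more transcripts of very low level in the controls rose. Without a filter, 427 of 6529 genes under 1 CPM in the control rose in Nito. In the other knockdowns 82 rose in Fl2d, 75 in CG7358, 72 in Vir and 4 in Ime4_dMettl14. Genes chosen for a low control level have little room to fall, so only the numbers that rose are set side by side. Depth is argued against: after thinning every library to 15743484 counts, the lowest Nito library still had 194 more genes than the highest other library. The pattern was graded. After thinning, the Fl2d, Vir and CG7358 libraries had 10600 to 10841 genes with a count, above the controls at 10482 to 10512. Read-through from an expressed gene upstream may contribute and stays open. Of the risen low genes 31.9% had a gene at 10 CPM or more within 5 kb upstream on the same strand, against 20.9% of the other low genes (Fisher's exact test, two-sided, p = 3.75e-07), but the opposite strand also showed 26.0% against 18.6% (p = 0.000348), so active surroundings and read-through cannot be told apart.

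In the libraries of Fl2d, replicate 2 held 409 CPM of FBgn0262735 and 298 CPM of FBgn0013984, against 103 to 116 and 154 to 166 in replicates 1 and 3, besides the level of Unr given above.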
